A study of Mus musculus with 2 samples.

How the data were processed

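Gene expression was measured in gastrocnemius muscle of male C57BL/6 mice, per the labels' protocols. Total RNA of 6 denervated mice was pooled into 1 sample and total RNA of 6 control mice into another, and each pool was hybridised to 1 array, so the series holds 2 arrays and no replicate array. Samples were grouped by their source label, and neither was left without a group. Both arrays lay on one slide and one scan, so position on the slide and group cannot be told apart.

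Per the labels, 1.65 µg of Cy3-labelled cRNA was fragmented for each 1-colour hybridisation. The spot intensity values in the deposited scanner files were made with Agilent Feature Extraction 9.5, per the submitters' processing notes, and the file headers give version 9.5.3.1. Per the file headers, each intensity was background-subtracted and detrended within its array, dim spots were set to a surrogate value, and no scaling between arrays was applied. The software's preset multiplicative error of 10% dominates its error for bright spots, per the file headers. The authors also deposited a value table whose whole-number values are used here as a score on a linear scale. Set against the scanner values, this deposited score is the processed intensity divided by the array's 75th percentile over all 45018 spots and multiplied so that the percentile is 100, then rounded. The ratio of score to intensity varied by 0.406% in the control column and 0.539% in the denervated column among spots above the rounding range. The column medians were 10 and 9. The scale, centring and direction of that table were thereby settled, and it served as an alternative only. No sample column of the table was left unused.

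Each array carried 43379 spots outside the control classes, which represent 41174 probes, 245 of them printed 10 times. Spots marked by the software as non-uniform or as population outliers were left out (87 on the control array and 81 on the denervated array), and spots of one probe were averaged on the log2 scale. The main value was log2 of the processed intensity minus the array's 75th percentile over these probes. The 75th percentile was 788 on the control array and 1063 on the denervated array. A probe counted as measured when it was well above background on both arrays and saturated on neither. A gene with several measured probes took the one with the highest mean signal, and the lowest and highest difference among its probes are given where they differ in sign or by which side of 2-fold they lie on. Genes above background on one array only received a bound. The bound sets the measured value against the higher of the dim probe's own signal and the lowest well-above-background signal of that array. No dim value was set below that level.

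Probe names follow the array design, with probe positions on the mm8 mouse assembly as the files give them. Of 41174 probes, 23366 were named through a RefSeq accession in a RefSeq table of assembly GRCm38.p6, used for names only, and this updated 4828 symbols. Other probes kept the file's name, which can be old. In all, 33984 probes carried a gene symbol, for 21585 symbols, and 7190 carried none.

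With 1 array per group there was no test and no p-value. A difference describes these 2 pools. The error printed with a log2 difference is the scanner software's spot error carried through both arrays. It is technical only and its median over genes was 0.20. Replicated spots gave a smaller figure: among 173 probes with at least 8 usable spots, the median SD of the log2 difference over spots was 0.06. Neither figure holds the spread between mice, which 1 array of pooled RNA per group cannot estimate. A fold of 2 was the threshold. Each of 33 gene lists, fixed before the data were examined, was summarised by its median log2 difference. The median was placed among 10000 random lists of the same size matched on mean signal in 20 bins. A list was said to stand apart when its median lay outside the central 95% of the random medians, and lists with under 5 measured members received no percentile. The percentile describes these 2 arrays.

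Genes named in the text were chosen by a rule also fixed before the data were examined. It takes the 10 highest and 10 lowest differences, leaving out clone, predicted and accession names. It adds 17 genes fixed in advance, the 3 members of each list with the largest absolute difference, the 2 brightest members of each fibre-type or cell-type list, and the 3 largest bounds in each direction. Some genes that the rule names are not reported here. Genes outside the rule are marked as chosen after their values were seen.

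Alternatives covered scaling (median of detected probes, quantile, signal-dependent loess centring, spike-in controls, none), background (normexp with offset 50 on raw intensities, in limma 3.58.1 under R 4.3.3) and the deposited table. They also covered dim probes (no filter, or at least 4 times the lowest detected signal), marked spots kept, and the mean of a gene's probes. A fold threshold of 1.5, a count over probes, unmatched random lists and list means completed the set. Taking the probe with the smallest absolute difference was added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. The steps were tested on simulated data in which 200 of 16422 genes received a planted difference, with noise of SD 0.2. All 50 genes planted at each of -3, -1.5, 1.5 and 3 passed 2-fold in the right direction, and 0% of the other genes did. Of 100 unchanged lists of 25 genes, 4 stood apart, and of 100 lists shifted by 0.5, 100 stood apart. The real log2 differences had an SD of 0.85 across genes, far wider than the simulated noise. The simulation therefore checks that the steps run correctly and gives no power or error rate for these data.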

Results

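Messenger RNA levels were compared between gastrocnemius muscle, a mixed but mostly fast-fibre calf muscle, of mice whose muscle had lost its nerve supply for 14 days and of control mice. One label calls the control a sham control and another only a control, so it is unclear whether the control mice were operated on. The mice were 7 weeks old at denervation and 9 weeks old at sampling. Each group was a pool of 6 mice on 1 array, so no difference below has a replicate check, and each describes these 2 pools. Of the 41174 probes, 70.9% were well above background on the control array and 68.4% on the denervated array. Log2 differences are denervated minus control, and the value after ± is the technical error.

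The comparison asks how the transcript profile of atrophying, denervated muscle differs from that of control muscle. The acetylcholine receptor subunits Chrng and Chrna1, myogenic factors, embryonic contractile genes, proteasome subunits and myeloid markers were higher in the denervated pool, and genes of glycolysis, mitochondrial respiration and fatty acid oxidation were lower. Of 15427 genes measured on both arrays, 1077 were at least 2-fold higher in the denervated pool and 1312 at least 2-fold lower. At 16-fold or more, 37 genes were higher and 17 lower. Of the genes past 2-fold, 45.1% were higher ones. Scaling to the spike-in controls moved every gene up by 0.40 and unscaled values by 0.43, and the share then became 78.1% and 80%, so differences between about -0.43 and 0 have no settled direction. For 5904 genes a second probe was measured. It lay on the same side of 0 for 355 of 395 higher genes and 385 of 398 lower genes, and passed 2-fold the same way for 239 and 241 of them.

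**Figure D1:**
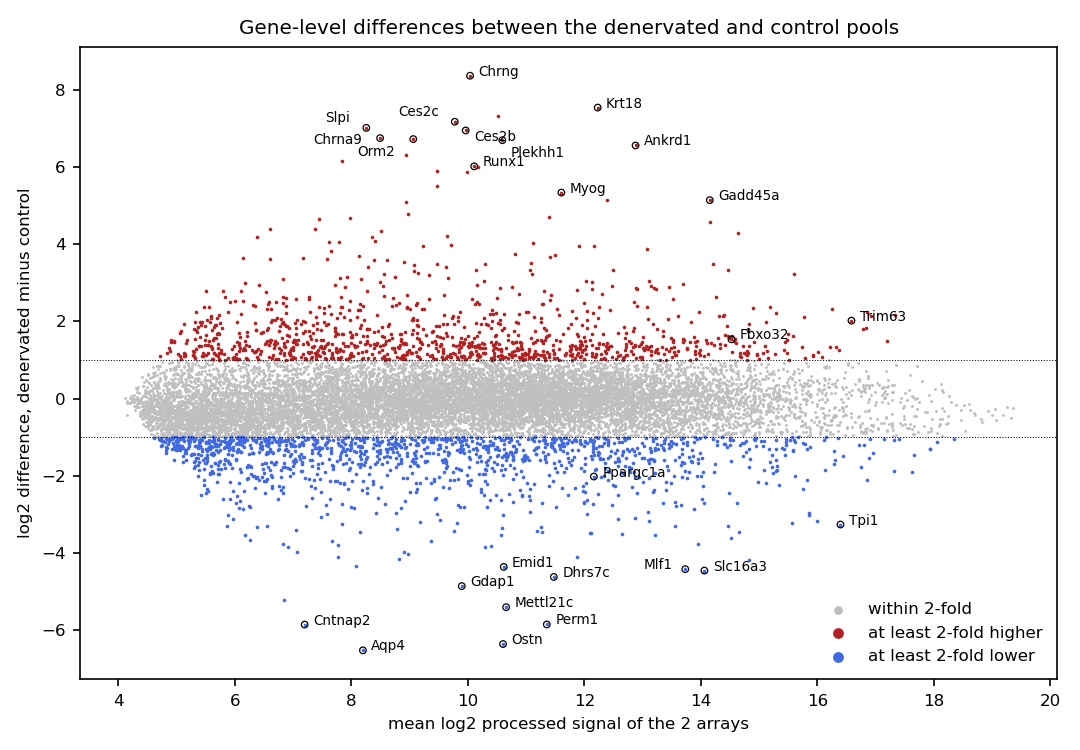
Log2 difference (denervated minus control) of each of 15427 genes against its mean log2 processed signal on the 2 arrays, with the dotted lines at 2-fold. Red points are the 1077 genes at least 2-fold higher and blue points the 1312 at least 2-fold lower, and the spread of differences narrows at the brightest signals on the right, around values below 0.

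The highest difference belonged to Chrng, the fetal gamma subunit of the muscle acetylcholine receptor. It was 8.37 ± 0.23 higher, with a signal of 49.9 in the control pool and 22201 in the denervated pool (transcript NM_009604, probe on chromosome 1 at 89042737 to 89042796, mm8). Its second probe gave 4.31. Keratin 18 (Krt18) followed at 7.54 ± 0.20. The carboxylesterases Ces2c and Ces2b differed by 7.17 ± 0.22 and 6.95 ± 0.22; as near relatives in one gene cluster they may share signal between probes. The protease inhibitor Slpi (7.02 ± 0.28), the acetylcholine receptor subunit Chrna9 (6.75 ± 0.26), the acute-phase protein Orm2 (6.72 ± 0.24), Plekhh1 (6.70 ± 0.21) and the stretch-responsive ankyrin repeat gene Ankrd1 (6.56 ± 0.20) were also among the 10 highest.

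At the other end, Aqp4, the water channel of fast fibres, was lower by 92.2-fold (-6.53 ± 0.27), with its second probe at -4.55. Ostn, which encodes the secreted peptide musclin, stood at -6.36 ± 0.21. Cntnap2 was at -5.86 ± 0.34 and Perm1, a muscle regulator of the PGC-1 and ERR programme, at -5.86 ± 0.20. Mettl21c (-5.41 ± 0.21), Gdap1 (-4.86 ± 0.21), Dhrs7c (-4.63 ± 0.20), the lactate transporter Slc16a3 (-4.46 ± 0.20), Mlf1 (-4.42 ± 0.20) and Emid1 (-4.36 ± 0.21) were the other genes among the 10 lowest.

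Above background on one array only were 409 genes in the denervated pool and 974 in the control pool, of which 171 and 326 had a bound of 2-fold or more. S100a8, a calcium-binding protein of myeloid cells, was at least 301-fold higher in the denervated pool, Orm3 at least 35.3-fold and Gsta2 at least 20.1-fold. The potassium channel gene Kcng4 was at least 32.2-fold higher in the control pool, Lrp2bp at least 29-fold and the muscle growth factor gene Fgf6 at least 23.4-fold.

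Of 26 measured denervation-response and neuromuscular junction genes, 13 were at least 2-fold higher and 4 at least 2-fold lower. The list's median of 0.76 lay above all 10000 random lists (percentile 100). The median was 1.16 with spike-in scaling, which shifts the random lists equally. It was 0.39 with no filter on dim probes and 0.37 with the smallest-difference probe, and stood apart in both cases. Beside Chrng, the myogenic factor Myog stood at 5.34 ± 0.20, the growth-arrest gene Gadd45a at 5.14 ± 0.20, and the receptor subunit Chrna1 at 4.57 ± 0.20 with a second probe at 3.19. The transcription factor Runx1 was at 6.02 ± 0.21 by its brighter probe and 1.27 by the other. The histone deacetylase Hdac4 (2.86 ± 0.20) and the junctional kinase Musk (2.32 ± 0.21) were also higher. The 4 lower members, named after their values were seen, were acetylcholinesterase (Ache, -2.32), the transcription cofactor Dach2 (-2.27), the histone deacetylase Hdac9 (-2.14) and the adult receptor subunit Chrne (-1.72).

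Protein breakdown genes were summarised by class, and each class was compared with random lists only. Of 35 proteasome subunits, 12 were at least 2-fold higher, none was 2-fold lower, and 33 were above 0, with a median of 0.91 (percentile 100). With spike-in scaling 29 were at least 2-fold higher (median 1.31). Psmd4 (1.46 ± 0.20), Psmc4 (1.44 ± 0.20) and Psmb3 (1.33 ± 0.20) had the largest differences. The list does not hold every subunit: Psmb10, outside it and named after its value was seen, was at -0.95. The ubiquitin ligase list as a whole did not stand apart: its median was 0.00 and 5 of 26 members were at least 2-fold higher. Those 5 included the muscle ligases Trim63 (MuRF1, 2.02 ± 0.20) and Fbxo32 (atrogin-1, 1.53 ± 0.20), with Fbxo30 at 1.24 ± 0.20 (0.96 to 1.64 over its probes). With spike-in scaling the list median was 0.40, with 21 members above 0 and 7 at least 2-fold higher. Of 39 autophagy and lysosome genes, 6 were at least 2-fold higher and 1 at least 2-fold lower (median 0.26, outside the random range), or 12 and none with spike-in scaling (median 0.67). The lysosomal protease gene Ctsl (2.12 ± 0.20), the proton pump subunit gene Atp6v1a (1.92 ± 0.20) and Ctss (1.75 ± 0.20) led them; Ctss is also abundant in macrophages, whose markers were higher too.

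Energy metabolism genes were lower as groups. All 72 measured oxidative phosphorylation subunits were below 0, 8 of them at least 2-fold lower, with a median of -0.72 and a percentile of 0. With spike-in scaling the median was -0.32, 71 of the 72 stayed below 0 and 1 was at least 2-fold lower. Cox7a1, a muscle isoform of cytochrome c oxidase, was at -1.54 ± 0.20, and Ndufb10 and Ndufb5 of complex I were both at -1.19 ± 0.20. All 25 tricarboxylic acid cycle and pyruvate dehydrogenase genes were below 0 and 6 were at least 2-fold lower (median -0.77, percentile 0). With spike-in scaling 23 were below 0 and 2 at least 2-fold lower (median -0.37). Idh2 (-2.67 ± 0.20), Idh3a (-1.47 ± 0.20) and Sdhb (-1.28 ± 0.20) were the lowest of these. Fatty acid genes had 9 of 30 members at least 2-fold lower and none higher (median -0.61), led by Acaa2 (-2.15 ± 0.20), Cpt1b, the carnitine transferase that admits fatty acids to mitochondria (-2.05 ± 0.20), and the transporter Slc27a1 (-1.86 ± 0.20). Their median was -0.20 with spike-in scaling, with 7 at least 2-fold lower and 9 above 0.

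Glycolysis and glycogen genes had the lowest median of the 33 lists, -1.22 (percentile 0), with 18 of 30 at least 2-fold lower. With spike-in scaling the median was -0.82 and 12 passed 2-fold. Pfkfb1 (-4.11 ± 0.20), triosephosphate isomerase Tpi1 (-3.27 ± 0.20) and glycerol-3-phosphate dehydrogenase Gpd1 (-3.02 ± 0.20) had the largest differences, while the glycogen branching enzyme gene Gbe1, named after its value was seen, stood at 1.31. The branched-chain amino acid list had a median of -0.49, with 2 of 22 members at least 2-fold lower. Its extreme members were Auh (-1.29 ± 0.20, with a second probe at 0.81), Ppm1k (-1.13 ± 0.20) and Aldh6a1 (-0.92 ± 0.20). This list stayed within the random range when genes took the mean of their probes. With spike-in scaling its median was -0.09, with 10 members above 0 and none 2-fold lower.

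Of 21 FoxO, PGC-1 and metabolic regulators, 9 were at least 2-fold lower and 1 at least 2-fold higher (median -0.80, percentile 0, or a median of -0.40 with spike-in scaling). The coactivator Ppargc1a was at -2.02 ± 0.20, the orphan receptor Nr4a1 at -3.63 ± 0.20 and the retinoid receptor Rxrg at -2.61 ± 0.20, and the higher gene was Foxo1 at 1.17 ± 0.20. Foxo3 was not settled. It was above background in the control pool only (at least 2.17-fold higher there), while 1 dim probe listed under its older name Foxo3a gave 0.23 ± 0.33.

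**Figure D2:**
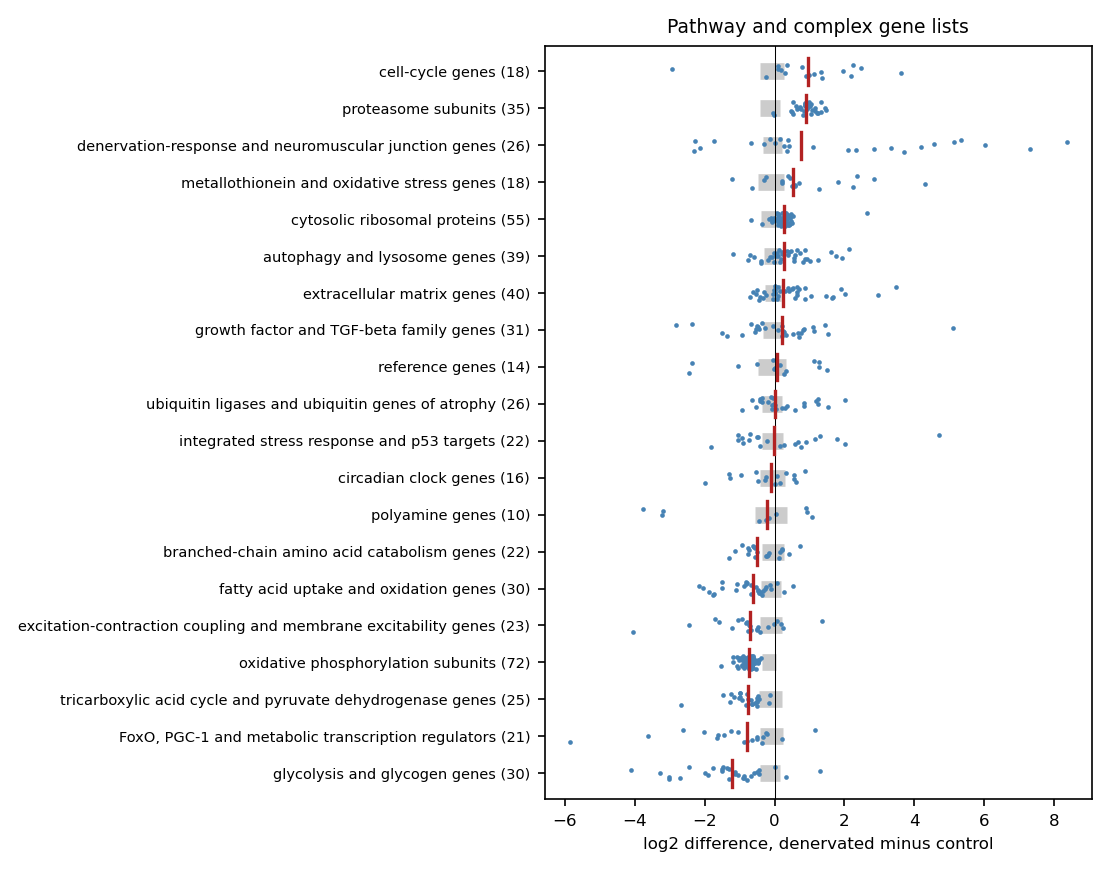
Log2 difference (denervated minus control) of each measured member of the pathway and complex lists (blue points, number measured in parentheses), with the list median (red bar) and the central 95% of medians of 10000 signal-matched random lists (grey band). Cell-cycle genes, proteasome subunits and denervation-response genes lie to the right with medians of 0.95, 0.91 and 0.76, and glycolysis genes farthest to the left at -1.22.

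Contractile genes were summarised in developmental and adult lists, which were not tested against each other. Of 13 embryonic and cardiac contractile and stretch-response genes, 8 were at least 2-fold higher and 2 at least 2-fold lower (median 2.14, percentile 100). Embryonic myosin Myh3 was at 5.14 ± 0.20, with its second probe at 5.39, and Ankrd2 at 3.24 ± 0.20. Cardiac actin Actc1, named after its value was seen, went the other way at -2.16. The neonatal myosin Myh8 had a signal near those of the adult fast myosins (516976 in the control pool, -0.28 ± 0.20, or 0.12 with spike-in scaling), and its probe may also bind these close relatives. Adult isoforms did not stand apart by their medians: the fast-fibre median was -0.55, with all 17 genes below 0 and 4 at least 2-fold lower, and the slow-fibre median -0.45 with 3 of 13 at least 2-fold lower. Both stood apart as list means (-0.78 and -0.66), and the fast-fibre median did so against unmatched lists and with the smallest-difference probe. With spike-in scaling these medians were -0.15 and -0.04. Myosin light chain kinase Mylk2 (-2.34 ± 0.20), Myoz1 (-1.88 ± 0.20) and Myoz3 (-1.82 ± 0.25) were the lowest fast-fibre genes. The lowest slow-fibre genes were Myl2 (-2.24 ± 0.20), Myl6b (-2.19 ± 0.20, with other probes up to 0.94) and Tnnc1 (-1.39 ± 0.20), and the brightest were Myl3 (-0.93 ± 0.20, with another probe at -2.13) and myoglobin (Mb, -0.45 ± 0.20). The main fast myosin Myh4 was at -0.30 ± 0.20 and turned positive under every scaling except the median one, and slow myosin Myh7 was at -0.73 ± 0.20. Troponins Tnnc2 (-0.50 ± 0.20) and Tnnt3 (-0.21 ± 0.20, positive under the same scalings as Myh4) were the brightest of the fast-fibre list. The median signal of the fast-fibre genes was 311878. Among genes with signals of 262144 to 524288 the SD of log2 differences was 0.37, against 0.85 at 32768 to 65536. A second Myh4 probe was saturated on both arrays.

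Excitation genes were lower as a list (median -0.70, or -0.29 with spike-in scaling, 6 of 23 at least 2-fold lower, 1 higher), led by the potassium channels Kcnc1 (-4.04 ± 0.21) and Kcna7 (-2.44 ± 0.20) and the junctional protein Jph2 (-1.70 ± 0.20). Among 15 myogenic regulators and satellite-cell markers, 4 were at least 2-fold higher and none 2-fold lower (median 0.59), or 7 and none with spike-in scaling (median 0.99). The 4 included Myod1 (2.71 ± 0.20) and Myf6 (2.20 ± 0.20), and the bright Mef2c differed by 0.40 ± 0.20 with its other probe at -0.62. Of 40 extracellular matrix genes, 8 were at least 2-fold higher and none 2-fold lower (median 0.23), or 14 and none with spike-in scaling (median 0.63). The protease inhibitor Timp1 (3.48 ± 0.20), osteopontin Spp1 (2.95 ± 0.20) and the collagen cross-linking enzyme Lox (2.03 ± 0.21) led, whereas the median fell within the random range with normexp background correction.

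Cell-type markers of the bulk tissue diverged. Of 25 macrophage and myeloid markers, all were above 0 and 24 at least 2-fold higher (median 1.48, percentile 100). Cd68 was at 3.53 ± 0.21, galectin-3 (Lgals3) at 2.56 ± 0.20 and the Fc receptor Fcgr1 at 2.21 ± 0.21 with its other probe at 0.77. The brightest were the lysozymes Lyz2 (1.48 ± 0.20) and Lyz1 (1.39 ± 0.20), close relatives. Endothelial markers had a median of -0.51 and smooth-muscle and pericyte markers of -0.71, both below the random range. Examples were Kdr (-1.12 ± 0.20), Sox18 (-0.79 ± 0.20), Emcn (-0.75 ± 0.20) and Flt1 (-0.73 ± 0.20) for endothelium, and Lmod1 (-0.99 ± 0.20), Kcnj8 (-0.91 ± 0.20), Tagln (-0.81 ± 0.20) and Rgs5 (-0.60 ± 0.20) for the vessel wall. The brightest members were the water channel Aqp1 (-0.42 ± 0.20, or 0.02 without scaling) and Acta2 (-0.54 ± 0.20), whose signal of 302075 may include other muscle actins. Spike-in scaling brought these medians to -0.11 and -0.31. Fibroblast markers did not stand apart (median -0.11, positive with spike-in scaling at 0.29), with Clec3b at -1.04 ± 0.20, Cxcl12 at -0.86 ± 0.20, Gsn at -0.61 ± 0.20 and Vim at 0.78 ± 0.20. Adipocyte markers had a median of -0.52 (-0.12 with spike-in scaling), with the lipid-droplet genes Plin4 at -1.90 ± 0.20, Plin1 at -0.95 ± 0.21 and Cidea at 1.85 ± 0.20. The brightest were the lipid-binding gene Fabp4 (-0.42 ± 0.20) and Car3 (-0.09 ± 0.20, or 0.31 with spike-in scaling, and 0.74 by its other probe). Control-pool signals were 31905 for Plin4 and 195729 for Car3, against 195 for Plin1. Which cells of the whole muscle gave these signals was not tested. Of 13 Schwann cell and nerve markers, 5 were at least 2-fold lower and 2 at least 2-fold higher (median -0.64, or -0.24 with spike-in scaling). This list lay within the random range when genes took the mean of their probes (median -0.37). The myelin genes Mal (-1.95 ± 0.28) and Pmp22 (-1.55 ± 0.20) were lower, S100b was at -0.04 ± 0.20 (0.36 with spike-in scaling), and the neurotrophin receptor Ngfr stood at 2.47 ± 0.21 by its brighter probe and -0.16 by the other. T-cell and B-cell markers were dim, with 6 of 13 measured (median -0.42, not apart), among them Cd3e (-0.55 ± 0.21), Cd3g (-0.46 ± 0.26) and Cd79b (-0.39 ± 0.23). Skin genes had 6 members measured and did not stand apart (median -0.46), with Trp63 at 1.62 ± 0.20, Krt10 at -1.35 ± 0.20 (other probe -0.68) and Lor at -0.99 ± 0.34. Red blood cell genes had 4 members measured, too few for a percentile, with Hba-a1 at -0.61 ± 0.20 and Alas2 at -0.53 ± 0.20.

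**Figure D3:**
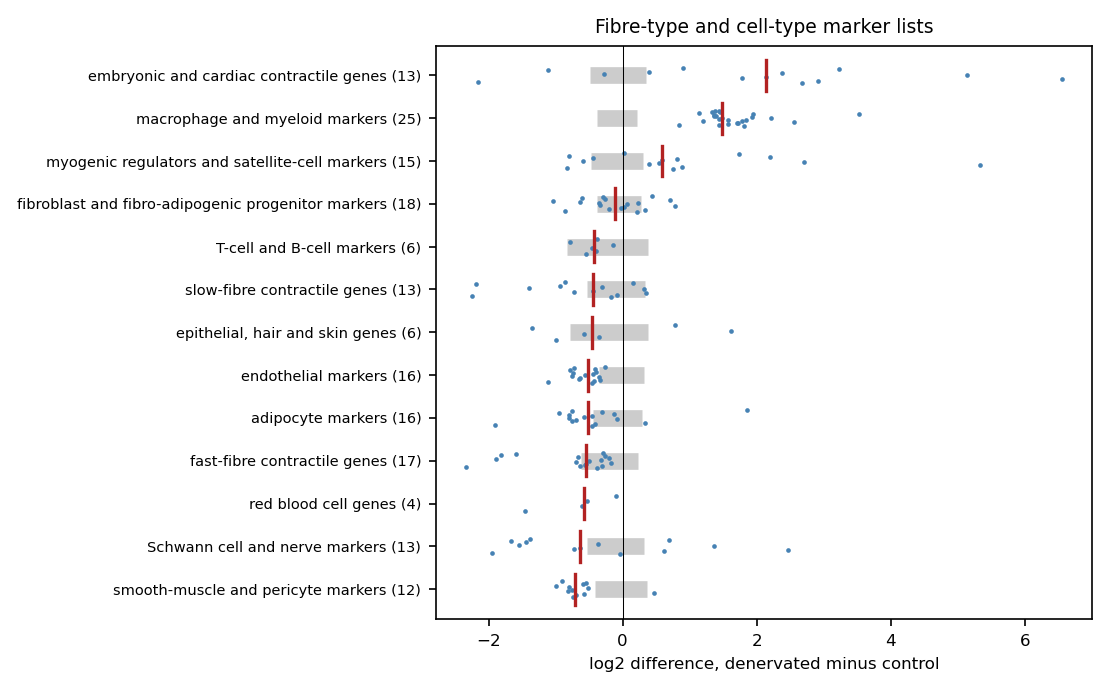
Log2 difference (denervated minus control) of each measured member of the fibre-type and cell-type lists (blue points, number measured in parentheses), with the list median (red bar) and the central 95% of medians of 10000 signal-matched random lists (grey band; none for red blood cell genes). The medians of embryonic contractile genes (2.14) and myeloid markers (1.48) lie to the right of their bands, and those of smooth-muscle and pericyte (-0.71) and endothelial (-0.51) markers to the left.

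Metallothionein and oxidative stress genes had 6 of 18 members at least 2-fold higher (median 0.54), with Mt2 at 4.29 ± 0.20, Mt1 at 2.83 ± 0.20 and thioredoxin Txn1 at 2.37 ± 0.20. Cell-cycle genes had 8 of 18 at least 2-fold higher (median 0.95), with Rrm2 at 3.63 ± 0.25 and Mki67 at 2.46 ± 0.21, and the mitotic kinase gene Aurka opposite at -2.94 ± 0.20. Cytosolic ribosomal protein genes had a median of 0.28 over 55 genes, of which 1 passed 2-fold, Rpl3 at 2.64 ± 0.20. The like-named Rpl3l, outside this list and named after its value was seen, was at -2.70. Within the list, Rpl10 was at 0.53 ± 0.20 and Rpl21 at -0.66 ± 0.20, with another probe at 0.68. Stress and p53 targets did not stand apart (median -0.02), although the cell-cycle inhibitor Cdkn1a was at 4.69 ± 0.20, Atf3 at 2.01 ± 0.20 and Gadd45b at -1.80 ± 0.20. Neither did polyamine genes by their median (-0.21), although their mean of -0.81 did, and spermine oxidase Smox (-3.76 ± 0.20), Amd2 (-3.23 ± 0.20) and its close relative Amd1 (-3.18 ± 0.20) were lower. Circadian genes (median -0.11) included Hlf at -1.99 ± 0.20, Bhlhe41 at -1.31 ± 0.21 and Nfil3 at -1.28 ± 0.20. The medians of the stress, polyamine and circadian lists were above 0 with spike-in scaling. The growth factor list (median 0.20, or 0.61 with spike-in scaling) lay at the edge of its random range, with Gdf5 at 5.09 ± 0.22, Fgfbp1 at -2.82 ± 0.21, the activin receptor Acvr2b at -2.36 ± 0.21 and myostatin (Mstn) at -0.50 ± 0.20. Common reference genes ranged widely. Actb was at 0.00 ± 0.20 (the file places its probe on chromosome X, and the other probe gave -0.18), Tubb5 at 1.49 ± 0.20, Tfrc at -2.35 ± 0.20 and Gapdh at -2.45 ± 0.23, the last from a dim probe with signals of 228 and 56.1.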

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

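No test was chosen after this result was seen, and no explanation was weighed. Probes without a gene symbol stayed outside the gene-level comparison, and 121 of the 3435 measured on both arrays were at least 2-fold higher in the denervated pool, against 357 at least 2-fold lower. The highest of them was 3.85 on the log2 scale, with its probe on chromosome 9 at 78124335 to 78124382 (mm8). The lowest was at -4.79, on chromosome 16 at 5102478 to 5102537.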

How the results depend on the processing

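Taking the probe with the smallest absolute difference was an alternative added after seeing the data. The number of genes at least 2-fold higher in the denervated pool, 1077, became 2256 with spike-in scaling, 2384 without scaling, 2316 at a 1.5-fold threshold and 1753 over all probes. The number of genes at least 2-fold lower in the denervated pool, 1312, became 632, 596, 3411 and 2240 in the same order, and 2518 with no filter on dim probes; the thresholds and units explain the last counts by construction, while the cause of the scaling shift was not tested. Because spike-in scaling raised every gene by 0.40, all 1077 higher genes were kept by construction, and 632 of the lower genes stayed past 2-fold. Under the other alternatives both counts stayed within 1.5 times. The share of higher genes among those past 2-fold was 53.7% with quantile and 54.6% with loess scaling.

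Median, spike-in and no scaling shift a list and its random lists alike, so a list could not change sides under them. The counts below include these fixed outcomes. Of the 13 gene lists of main interest over 14 alternatives each, 173 of 182 list medians kept their side of the random range, and for the other 19 lists with a percentile 255 of 264 did. Their 9 changes were the growth factor list standing apart 4 times (0.20 to 0.21), the polyamine list as a mean (-0.81), the adipocyte list within its range as a mean (-0.43), and the Schwann cell list within it with no filter (-0.21), the mean of probes (-0.37) and as a mean (-0.36). The branched-chain amino acid median came within the range with the mean of a gene's probes (-0.33), with the smallest-difference probe (-0.28) and as a list mean (-0.36). The extracellular matrix median came within it with normexp (0.12) and with the strict filter on dim probes (0.15). The fast-fibre list stood apart with the smallest-difference probe and against unmatched lists (-0.55 in both), and as a list mean (-0.78), and the slow-fibre list as a mean (-0.66). The cause was not tested. Of 1711 values of 144 named genes under alternatives, 1671 kept their side of 2-fold, 34 came within 2-fold and 3 passed it. Among the 1671, 28 values of 12 genes within 2-fold had the opposite sign, mostly under other scalings. The other 3, past 2-fold by their main value, reversed with the smallest-difference probe: Auh (0.81), Myl6b (0.065) and Ngfr (-0.16). No paired analysis was possible because each group is 1 array and the result comes from no test. Detection limits what can be said of dim genes: 6158 symbols were not measured on both arrays.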

Other observations

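These genes and groups were picked after their values were seen, as were the tests of fibre dilution, of Schwann cell loss and of genes as bright as the fast-fibre median. Beta-tubulin genes were higher together: 6 of 7 measured genes with names beginning Tubb were at least 2-fold higher (median 1.49), led by Tubb6 at 3.34, although a second Tubb6 probe gave -0.58. The muscle and testis alpha-tubulin Tuba8 was at -1.63. The chaperonin subunits that fold tubulin and actin had a median of 0.71 over 8 Cct genes. Among 332 families of at least 6 genes formed by name stem, 43 lay outside the random range. The count would be 16.6 if family members varied independently, which related genes need not do. Some of these families, such as Psmd and Ndufb, overlap the lists described above. Olfactory receptor genes, which sit close to background here, had a median of -0.50 over 247 genes, below the central 95% of signal-matched lists (-0.40 to -0.24). The 5 dimmest of 20 signal bins were also the lowest, with medians from -0.40 to -0.25. The median over all genes was -0.11 and that of the brightest bin -0.17, so lying below 0 was not particular to dim genes.

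Krt8, the partner of Krt18, was at 6.31, whereas Krt19 was at -0.24, and Epcam and Cdh1 were not well above background on both arrays. Orm1 stood at 4.69 and Serpina3n at 4.07. Whether the probes of the like-named Orm1, Orm2 and Orm3 share signal was not tested, so their differences may not be separate results. S100a8 had a signal of 7488 in the denervated pool, while S100a9, with which it forms a heterodimer, differed by 1.37 only. From the imprinted genes, H19 was at 1.98, its neighbour Igf2 at -0.54, Dlk1 at -1.32 and Rian at -2.04.

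Myeloid markers were higher in the denervated pool by a median of 1.48. By itself, a smaller share of fibre RNA would raise the markers of every other cell type alike. The highest median among the endothelial, smooth-muscle and pericyte, and fibroblast lists was -0.11, which argues against it as the sole cause. These values cannot exclude a smaller fibre share that was offset in those lists by a loss of their own cells. With spike-in scaling the fibroblast median, the highest of these, was 0.29, and without scaling 0.32, against a myeloid median of 1.89 with spike-in scaling. A signal-dependent difference between the arrays was also argued against, since the myeloid median was 1.597 after signal-dependent centring. More myeloid cells, or higher expression in those present, may account for it as a hypothesis. Neither was tested: RNA of whole muscle does not separate cell number from expression per cell, and each group was 1 pool.

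Myelin genes were lower (6 genes, median -1.498, from -1.95 to -0.73), although Mbp probes ranged from -1.38 to 1.87. If fewer Schwann cells were the whole cause, other genes of the lineage would be as low. The 4 measured ones had a median of 0.65 by their brightest probes, and without Ngfr, whose other probe gave -0.16, the median was 0.62. A lower myelin programme in Schwann cells that remain is therefore a hypothesis consistent with these values, and with few markers and 1 pool per group it was not tested further.

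The fast-fibre genes at least as bright as their median signal lay close to no difference before scaling, with a largest unscaled difference of 0.26 in size; after 75th-percentile scaling all were below 0, but not after quantile or loess scaling. A test written before its result was seen, over the brightest twentieth of genes, argued against a compressed response: their interquartile range was 1.22 times that of the middle signal bins. The wording of that explanation was narrowed to the brightest twentieth after the result was seen. That group begins at a signal of 27184, far below the fast-fibre median of 311878. In a narrower test, made only after the wider one had come out against compression, 13 genes lay outside the contractile lists and were at least as bright as that median. The ratio was 0.48, as a compressed response near the top of the scanner range would give. Real differences of the brightest fibre genes may therefore be larger than measured, and truly steady levels of abundant transcripts remain open as well.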
